A study of Arabidopsis thaliana with 24 samples.

How the data were processed

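Total RNA from rosettes and roots of Arabidopsis thaliana was profiled on 24 single-colour Affymetrix arrays. The plants were Col-0, the reference accession, and rpt2-3a, a mutant named after RPT2, an ATPase subunit of the proteasome's regulatory particle. RNA was extracted with TRI Reagent, treated with TURBO DNase and labelled with the Affymetrix WT terminal labelling kit, per the labels' protocols. The labels put each array into 1 of 8 groups of 3 by organ, genotype and sulfur supply, and the series' design text calls the arrays of a group biological replicates.

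The only file used was the series' value table, which holds 28583 features and 1 value per feature and array, to 2 decimals. The deposited values run from 0.93 to 12.77 and were read as log2 expression values. The submitters' processing notes name Transcriptome Analysis Console. Its version, the summarisation and normalization method, the log base and the genome build are not given in the sources used here, so scale and centring of the values stay unknown and every fold change assumes base 2. The median value per array lay between 4.03 and 4.14 in rosettes and between 4.47 and 4.55 in roots. An array gives no count depth, and the number of arrays limits the precision. No scan date or batch was given, so array batches could not be examined. Within groups the arrays correlated across features with r from 0.989 to 0.994, and at least 97.8% of values differed between any 2 arrays of a group, so no array was a copy of another.

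Features were named through the platform annotation given with the series. In it 16746 features carried exactly 1 gene, 758 several and 11079 none. Of the features with 1 gene, 16601 were matched by gene identifier to the RefSeq gene table of TAIR10.1, which supplied current symbols and loci, and the others kept a locus name of the platform annotation where it gave one. The features with a locus covered 16512 distinct loci, of which 162 had more than 1 feature. Features with several genes or none were tested and counted but given no gene name. Symbols of listed genes are those of the lists. No coordinates were used.

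Tests were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the deposited log2 values without further normalization or filtering. Each organ had its own fit with 1 mean for each of its 4 groups over 12 arrays, which leaves 8 residual degrees of freedom. The difference between organs used all 24 arrays and 16 residual degrees of freedom. The 11 comparisons were the sulfur response of each genotype, the genotype difference at each supply and the difference of the sulfur responses between genotypes, in each organ, and the difference of the Col-0 response between organs. A feature passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors of log2 changes are the fit's standard errors (SE).

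Comparisons, gene lists, named genes and the alternatives were chosen before the data were examined. Among features with exactly 1 gene that passed and whose 2 groups of arrays did not overlap, the 10 highest and 10 lowest log2 changes were named, with every measured member of the sulfur marker list and up to 4 members, by smallest p, of each other list described. For differences of responses, passing the test was enough, and where nothing passed the 5 smallest p were named. RPT2A, RPT2B, NAC53, NAC78 and SLIM1 were also to be named, but none of them is among the named features used here. Complete separation of 3 against 3 arrays occurs by chance in 10% of features. A listed locus counts as measured where the annotation gave it a feature with exactly 1 gene. Whether a locus not measured has a feature among those with several genes or none is unknown here. Of 381 listed loci 62 were measured, each through its brightest feature in the organ, and 8 of 21 lists had at least 3 members. These 8 were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. The lists for sulfate transporters, phosphate starvation, nitrate response and senescence had 0 measured members in this sense. Those for indolic glucosinolates (UGT74B1), jasmonate (PDF1.2), salicylate (SAG101) and the clock (GI) had 1 each, so that a p adjusted over the list alone is there the unadjusted p. A further 5 sets of genes, for hypoxia, rapid wounding, class III peroxidases, cytosolic ribosomal proteins and germin-like proteins, were written after the first results had been seen, without the loci that had prompted them.

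The fit was tested on simulated data with the spread of the real arrays and 200 changed features of 28583. Each value was drawn independently, without correlation between features or effects shared by an array. The false calls of the simulation therefore do not measure the error rate in the real data. For the Col-0 rosette response it recovered 13.4% of features changed 1.41-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, with 4 false calls among 138. For the difference of responses between genotypes it recovered 59.7% of 2-fold differences in rosettes and 64.2% in roots.

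Alternatives were centring each array on its median, quantile normalization within the organ, leaving out features under the 25th percentile of mean log2, testing only features with exactly 1 gene, fitting all 24 arrays together, fitting only the 2 groups compared, the replicate number as a block, eBayes with trend and robust, array weights, a 2-fold threshold with or without adjustment of p, the mean of all features of a locus for listed genes, and leaving out each array in turn.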

Results

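Rosettes and roots of Arabidopsis thaliana were compared between Col-0 and the mutant rpt2-3a at normal and deficient sulfur supply. The plants grew in hydroponic culture in short days, with 8 h of light and 16 h of darkness. After 5 weeks on complete medium they stayed on it or spent 5 days on medium deficient in sulfur. Each combination of organ, genotype and supply had 3 arrays. The values are log2 expression values for 28583 features, of which 16746 carry exactly 1 gene.

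Organ markers followed the organ named for each array. The photosynthesis genes RCA, the activase of Rubisco, and PSAE1, a subunit of photosystem I, averaged 10.9 and 11.34 over the 12 rosette arrays against 3.86 and 2.97 over the 12 root arrays. EXPA7, a root hair expansin, averaged 2.18 in rosettes and 7.66 in roots, and no array of one organ reached the range of the other for these genes. RPT2A and RPT2B are not among the named features, so the mutated gene did not check the genotype labels.

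**Figure D1:**
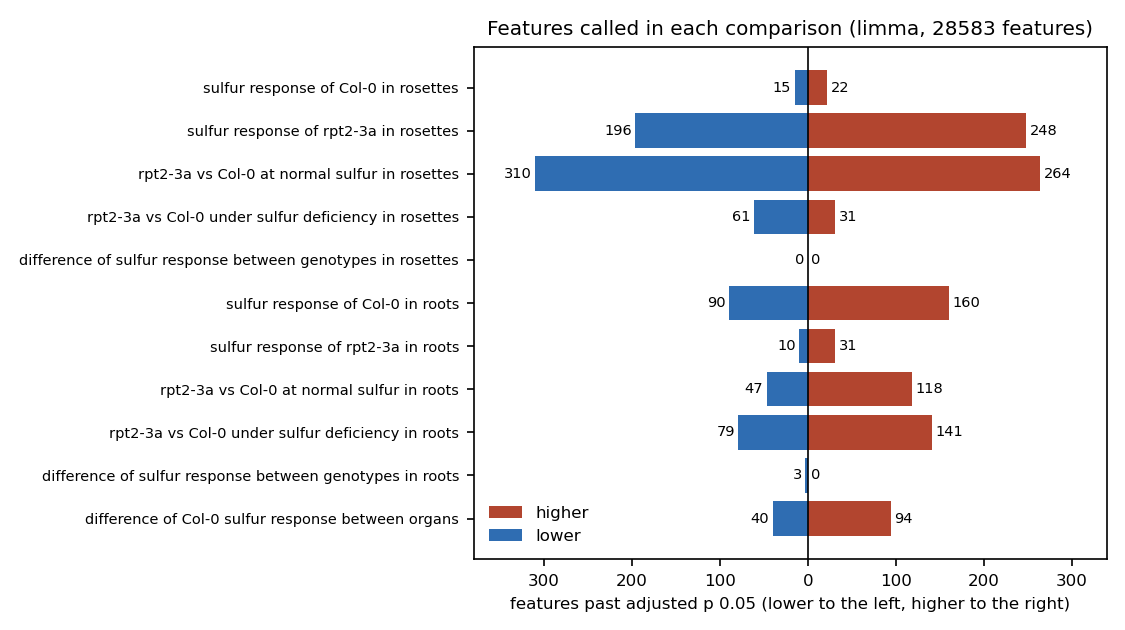
Number of features past an adjusted p of 0.05 in each of the 11 comparisons, with features that were lower drawn to the left and higher to the right. Counts ran from 0 for the difference of responses in rosettes to 574 for the genotype difference in rosettes at normal supply.

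In Col-0 roots, which genes respond to sulfur deficiency was asked first. Among unnamed features, chosen after their values were seen, 13537205 rose by 3.61 ± 0.2 SE (limma adjusted p = 9e-07). The unnamed feature 13412890 fell, at -2.76 ± 0.11 (adjusted p = 5.4e-08). The genes below are those of features with exactly 1 gene. AT1G75290, an isoflavone reductase-like gene, rose 8.46-fold, from 3.34 ± 0.59 to 6.42 ± 0.16 (mean log2 ± SD, n = 3; log2 change 3.08 ± 0.23 SE, adjusted p = 1.2e-05). AT4G37220, of the cold-acclimation WCOR413 family, rose 6.65-fold (2.73 ± 0.15, adjusted p = 9e-07) and AT4G31330 rose 4.45-fold (2.15 ± 0.14, adjusted p = 3.9e-06). AT3G10040, which encodes the hypoxia-responsive trihelix factor HRA1, rose by 2.41 ± 0.31 on the log2 scale (adjusted p = 0.0016). AT4G25410 (1.73), AT5G49750 (1.66), AT4G19800 (1.63), AT3G27220 (1.55) and AT2G32487 (1.54) rose as well. Among genes that fell were AT1G72900 (-1.64), the transporter-like genes AT1G61890 (-1.56) and AT5G52050 (-1.23), AT2G36690 (-1.31), AT3G50190 (-1.03), AT1G14480 (-1.01), AT5G52020 (-1), AT2G25460 (-0.99), AT2G25450 (-0.99), whose enzyme GSL-OH modifies aliphatic glucosinolates, and AT5G19700 (-0.89).

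Both measured members of the 12 sulfur deficiency markers rose in Col-0 roots, also when adjusted over the list alone. BGLU28, a beta-glucosidase, rose 4.31-fold from 2.71 ± 0.21 to 4.82 ± 0.7 (n = 3; 2.11 ± 0.28 SE, adjusted p = 0.0024), and SDI2 (AT1G04770) rose by 1.13 ± 0.17 (adjusted p = 0.0042). Of 3 measured genes of sulfate assimilation, the ATP sulfurylase gene APS3 rose (0.69 ± 0.13, adjusted p = 0.028), while APS4 (-0.31, adjusted p = 0.41) and SIR (-0.04) did not pass. Adjusted over the list alone APS3 passed as higher and APS4 as lower, and camera gave the list an adjusted p of 0.74. Of 2 measured aliphatic glucosinolate genes, GSTU20 fell (-0.72, adjusted p = 0.02) and UGT74C1 stood at -0.62 (adjusted p = 0.065), and both passed as lower when adjusted over the list alone. HSP15.7 (-0.42), LBD29 (-0.39) and PYE (-0.41), of the heat shock, auxin and iron lists, passed only when adjusted over their own lists alone. In total 250 features passed, 160 higher and 90 lower, of which 88 changed at least 2-fold and 121 carried 1 gene. The split was 139 to 117 after centring each array on its median and 139 to 107 after quantile normalization. Leaving out replicates 1 and 2 of deficient Col-0 left 139 and 158 features and leaving out replicate 1 at normal supply left 148. Of the 21 genes named as passing by the rule, 16 passed in all 6 fits without 1 array, and AT1G72900, AT5G49750, AT5G19700, AT5G52020 and AT4G19800 did not.

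In rpt2-3a roots the same question gave 41 features, 31 higher and 10 lower, of which 25 changed at least 2-fold and 17 carried 1 gene. AT5G10040 rose 3.07-fold, from 4.87 ± 0.23 to 6.49 ± 0.12 (n = 3; 1.62 ± 0.13 SE, adjusted p = 9.1e-05). AT1G75290 rose by 1.42 ± 0.23 (adjusted p = 0.025) and AT4G37220 by 1.4 ± 0.15 (adjusted p = 0.0019). Of the unnamed features given for Col-0, 13412890 stood at -2.3 ± 0.11 (adjusted p = 5.7e-07). The other, 13537205, rose by 1.7 ± 0.2 (adjusted p = 0.0036). Higher too were AT4G30380 (1.51), AT1G72540 (1.36), AT4G10265 (1.3), AT5G35525 (1.17), AT1G34510 (1.08), AT4G19760 (1.08) and AT4G25410 (1.07), and the lectin gene JAL22 (-1.04) and AT1G52700 (-0.98) fell. Neither sulfur marker passed, with SDI2 at 0.24 (adjusted p = 0.76) and BGLU28 at 0.56 (adjusted p = 0.62), nor did they when adjusted over the list alone. GSTU20 stood at -0.56 (adjusted p = 0.14) and UGT74C1 at -0.32, both lower when adjusted over the list alone. SAG101 (-0.34), the 1 measured gene of the salicylate list, passed only when adjusted over its list alone, which for 1 gene is its unadjusted p.

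By camera 4 lists shifted in rpt2-3a roots under deficiency, though no member passed singly and each call was lost with an estimated correlation. Flavonoid and anthocyanin genes had a median of -0.43 (adjusted p = 0.014, and adjusted p = 0.13 with an estimated correlation), with UGT79B1 at -0.42 and UGT75C1 at -0.44 lower when adjusted over the list alone. The 4 photosynthesis genes had a median of -0.39 (adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation), with RCA at -0.57 lower when adjusted over the list alone. Over the root arrays ATPC1, PSAE1 and RCA averaged 2.26, 2.97 and 3.86, under the array medians, and LHCB4.1 averaged 4.96. Whether the dim ones were detected in roots is open. Auxin response genes had a median of 0.107 (adjusted p = 0.04, and adjusted p = 0.13 with an estimated correlation), with GH3.3 at 0.41 higher when adjusted over the list alone. The 3 heat shock genes had a median of 0.333 (adjusted p = 0.044, and adjusted p = 0.13 with an estimated correlation), with HSP15.7 at 0.33 and HSP23.5 at 0.43 higher when adjusted over the list alone. Leaving out replicates 2 and 3 of deficient rpt2-3a left 10 and 22 called features, and replicates 1 and 2 at normal supply 13 and 26. Of the 12 named genes only AT5G10040, AT4G37220 and AT1G52700 passed in all 6 fits without 1 array.

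The root responses of the genotypes shared 18 features that rose, among them AT1G75290, AT4G37220, AT4G25410, AT5G10040, AT4G19760, AT1G72540, AT5G35525 and the methionine sulfoxide reductase gene MSRB5, against 0.17 for independent lists. Another 5 fell in both against 0.031, and 0 moved in opposite directions. Of the 250 features called in Col-0, 232 (92.8%) had the same sign in rpt2-3a, with a median change of 0.81 in Col-0 and 0.42 in rpt2-3a. Of the 41 called in rpt2-3a, 39 (95.1%) had the same sign in Col-0, with medians of 1.08 and 0.84. A feature called in one genotype tends to measure smaller in the other by that choice alone. The pair of responses shares no arrays. Of the 23 shared features 8 and 13 were left without replicates 2 and 3 of deficient rpt2-3a, and 9 without replicate 1 of rpt2-3a at normal supply.

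Whether the root response differed between genotypes was tested directly, and 3 features passed, all with a smaller rise in rpt2-3a. AT4G31330 rose from 4.07 ± 0.09 to 6.22 ± 0.06 in Col-0 and stood at 4.34 ± 0.31 and 4.9 ± 0.17 in rpt2-3a (n = 3 each; difference of responses -1.6 ± 0.2 SE, adjusted p = 0.022). The unnamed features 13499857 (-1.63) and 13375843 (-1.17), chosen after their values were seen, also passed. SDI2 had a difference of -0.89 ± 0.23 (adjusted p = 0.69) and BGLU28 of -1.55 ± 0.4 (adjusted p = 0.68), and both passed as lower when adjusted over the list alone (adjusted p = 0.0021 each). By camera heat shock genes (median 0.437, adjusted p = 0.022, and adjusted p = 0.13 with an estimated correlation) and auxin response genes (median 0.123, adjusted p = 0.029, and adjusted p = 0.13 with an estimated correlation) shifted up, led by HSP15.7 (0.75) and LBD29 (0.56), which passed only when adjusted over their lists alone. Photosynthesis genes, mostly dim in roots, shifted down (median -0.495, adjusted p = 0.029, and adjusted p = 0.34 with an estimated correlation), with no member passing. The call of AT4G31330 was lost in 10 of 12 fits without 1 array (adjusted p from 0.056 to 0.11), and held without replicate 3 of rpt2-3a at normal supply (adjusted p = 0.0033) and without replicate 3 of deficient Col-0, while the other 8 settings gave adjusted p from 0.0031 to 0.036. The count of 3 became 0, 0 and 1 without replicates 1, 2 and 3 of deficient rpt2-3a, and 1, 0 and 1 without those at normal supply. It became 0, 0 and 5 without replicates 1, 2 and 3 of deficient Col-0, and 0, 1 and 0 without those at normal supply, and 1558 features had an unadjusted p under 0.05.

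**Figure D2:**
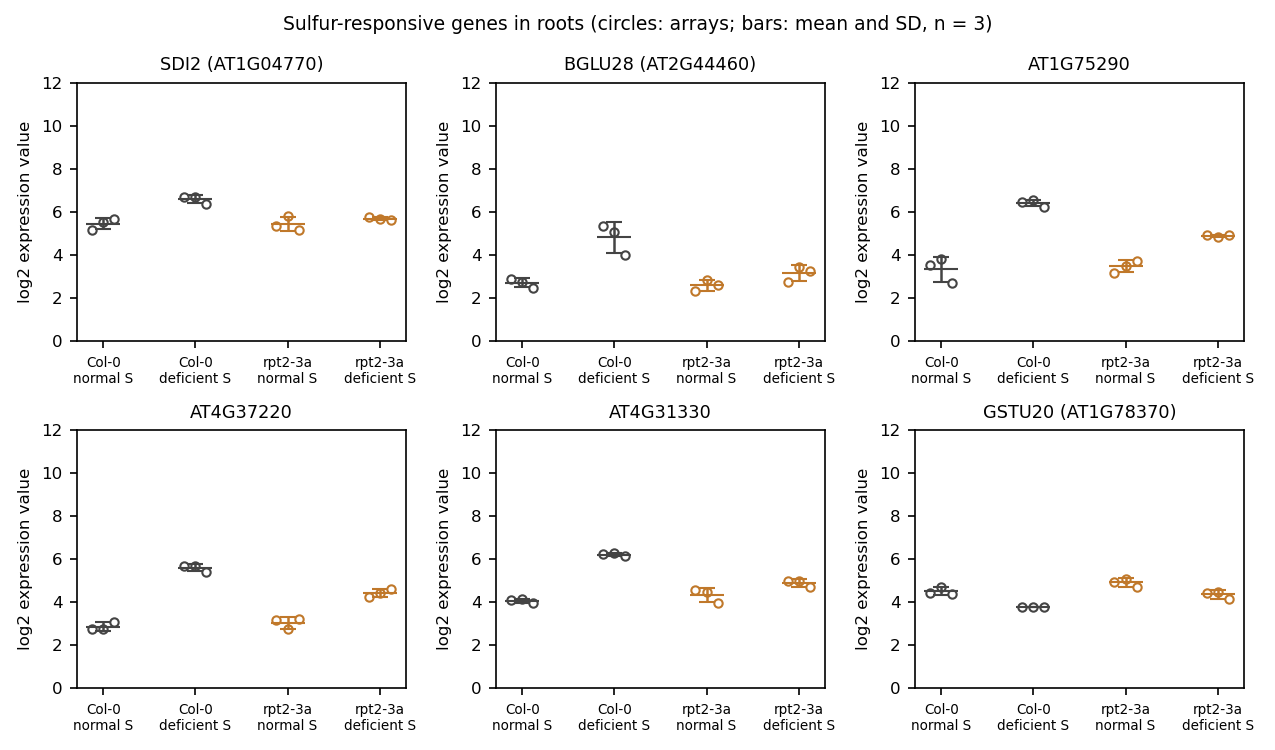
Log2 expression values of 6 genes in roots by genotype and sulfur supply, with arrays as circles and the mean and SD of 3 arrays as bars. SDI2, BGLU28, AT1G75290, AT4G37220 and AT4G31330 rose in Col-0 under deficiency, and all 5 were lower in deficient rpt2-3a than in deficient Col-0.

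In Col-0 rosettes 37 features passed under sulfur deficiency, 22 higher and 15 lower, of which 15 changed at least 2-fold and 14 carried 1 gene. ORA47, a jasmonate-associated AP2/ERF factor, fell from 7.37 ± 0.15 to 5.56 ± 0.47 (n = 3; -1.81 ± 0.25 SE, adjusted p = 0.015). GSTU20 fell from 8.17 ± 0.18 to 7.2 ± 0.18 (-0.97 ± 0.12, adjusted p = 0.011), as did AT4G30400 (-0.82), TZP (-0.78) and AT3G21460 (-0.67). AT3G56200, of an amino acid transporter family, rose by 1.06 ± 0.13 (adjusted p = 0.0081), and AT5G56880 (1.37), AT5G52882 (1.01), AT5G54300 (0.89), ABR1 (0.83), AT5G52410 (0.77), AT4G15260 (0.75), the cold- and clock-regulated COR27 (0.65) and AT4G38810 (0.58) rose too. Neither sulfur marker passed over all features, with BGLU28 at 1.43 ± 0.28 (adjusted p = 0.078) and SDI2 at -0.49 ± 0.19 (adjusted p = 0.5). Adjusted over the list alone BGLU28 passed as higher and SDI2 as lower. Of the aliphatic glucosinolate list GSTU20 passed and UGT74C1 stood at -0.62 (adjusted p = 0.056), both lower when adjusted over the list alone. APS4 (-0.4), UGT74B1 (-0.28) of the indolic glucosinolate list and AUR2 (-0.25) of the cell cycle list passed only when adjusted over their lists alone. None of the 8 lists fixed beforehand and tested by camera shifted, the smallest adjusted p being 0.075 for autophagy. Leaving out replicates 1, 2 and 3 of deficient Col-0 left 12, 18 and 12 features, and replicates 1 and 2 at normal supply 12 and 5. Of the 14 named genes only AT3G56200 passed in all 6 fits without 1 array.

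In rpt2-3a rosettes 444 features passed under deficiency, 248 higher and 196 lower, of which 114 changed at least 2-fold and 182 carried 1 gene, and fitting only the 2 groups gave 150 higher and 187 lower. Lower genes included AT1G33760, an ERF factor (-2.45 ± 0.37 SE, adjusted p = 0.0065), the EF-hand gene AT4G27280 (-2.07), AT4G29780 (-1.93), the TIR-domain genes AT1G72920 (-1.89) and AT1G72900 (-1.59), AT2G43590 (-1.87), AT5G52050 (-1.75), AT1G07135 (-1.72), AT3G02840 (-1.69) and AT2G39650 (-1.43). AT4G17470 rose from 5.02 ± 0.48 to 7.08 ± 0.57 (n = 3; 2.06 ± 0.32 SE, adjusted p = 0.0066). The B3-domain factor NGA3 (1.67), AT2G15830 (1.58), AT3G56260 (1.44), FAMT (1.37), AT1G52720 (1.19), AT1G30320 (1.15), AT5G19100 (1.1), the type-A response regulator ARR15 (1.09) and AT5G52882 (1.05) rose as well. SDI2 stood at -0.72 ± 0.19 (adjusted p = 0.095), lower when adjusted over the list alone, and BGLU28 at 0.13 ± 0.28 (adjusted p = 0.9). The 12 autophagy genes shifted up by camera with a median of 0.213 (adjusted p = 0.0014, and adjusted p = 0.057 with an estimated correlation). Of these 0 passed singly by limma, over all features or adjusted over the list alone, the smallest p being those of ATG8E (0.52) and ATG8I (0.28). 5MAT (0.41), of the flavonoid list, and PYE (0.35), of the iron list, passed only when adjusted over their lists alone. Leaving out replicates 1, 2 and 3 of deficient rpt2-3a left 226, 179 and 197 features, and replicates 1 and 2 at normal supply 272 and 207. Of the 20 named genes 14 passed in all 6 fits without 1 array, and FAMT, ARR15, AT4G27280, AT4G29780, AT1G72920 and AT2G43590 did not.

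Both rosette responses shared 9 features that rose, among them AT3G56200, AT4G38810, AT5G52410, AT5G52882, AT5G54300 and COR27, against 0.19 for independent lists, and 5 that fell, among them ORA47 and TZP, against 0.1. Of the 37 features called in Col-0, 34 (91.9%) had the same sign in rpt2-3a, and of the 444 called in rpt2-3a, 332 (74.8%) had the same sign in Col-0, with a median of 0.81 in rpt2-3a and 0.15 in Col-0. Leaving out replicates 1, 2 and 3 changed the 14 shared features to 3, 5 and 5 for deficient Col-0, 4, 2 and 9 for Col-0 at normal supply, and 3, 2 and 2 for deficient rpt2-3a. Without replicates 1 and 2 of rpt2-3a at normal supply 4 were shared each.

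The test of whether the rosette response differed between genotypes by limma gave 0 features at an adjusted p under 0.05, the smallest being 0.127, while 2650 had an unadjusted p under 0.05. The 5 smallest p were those of AT4G30400 (0.99 ± 0.16 SE), AT3G07195 (-1.19 ± 0.2), AT5G41180 (-0.9 ± 0.16), CYP71B32 (-1.08 ± 0.19) and AT5G44565 (-1.11 ± 0.19), each with an adjusted p of 0.13. BGLU28 stood at -1.31 ± 0.4 and GSTU20 at 0.73 ± 0.17 (adjusted p = 0.23), and these, UGT74C1 (0.46), UGT74B1 (0.42) and 5MAT (0.57) passed only when adjusted over their lists alone. SDI2 stood at -0.23. The count was 69 with all 24 arrays in one fit, 19 with eBayes with trend and robust, and 0 with array weights or the replicate block, so a response in one genotype's list and not in the other's is not shown to differ.

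In rosettes at normal supply 574 features differed between genotypes, 264 higher and 310 lower in rpt2-3a, of which 129 differed at least 2-fold and 280 carried 1 gene. Centring each array on its median turned the balance to 316 higher and 257 lower, and quantile normalization to 305 and 286. Fitting only the 2 groups compared gave 101 features here and 122 under deficiency, so the order of these counts depends on the fit. AT3G01345 was lower the most, at 3.83 ± 0.53 in rpt2-3a and 9.87 ± 0.11 in Col-0 (n = 3; -6.04 ± 0.26 SE, adjusted p = 1.8e-07). ORA47 was lower too (-2.04 ± 0.25, adjusted p = 0.0045), as were AT1G73325 (-2.15), AT4G17470 (-1.87), AT2G24040 (-1.66), AT1G66100 (-1.57), AT5G24155 (-1.46), TBL26 (-1.41), the JmjC-domain gene AT1G62310 (-1.34) and AT5G36550 (-1.33). Higher in rpt2-3a were AT3G48640 (2.65 ± 0.34, adjusted p = 0.0045), AT3G22235 (2.46), AT1G66810, a CCCH zinc finger gene (2.38 ± 0.19, adjusted p = 0.00011), AT2G43590 (1.97), AT3G23550 (1.82), AT5G57760 (1.7), AT1G27020 (1.65), EXO (1.52), AT4G39830 (1.51) and AT5G44570 (1.4). Of 4 measured flavonoid and anthocyanin genes, 5MAT was lower (-0.57, adjusted p = 0.038), and DFR (-0.71) and UGT75C1 (-0.49) joined it when adjusted over the list alone. By camera the list had a median of -0.528 (adjusted p = 0.0034, and adjusted p = 0.33 with an estimated correlation). ATG8F was lower (-0.62, adjusted p = 0.022), alone among 12 autophagy genes, also when adjusted over the list alone. PDF1.2 (2.27 ± 1.04, adjusted p = 0.35), SAG101 (0.44), SDI2 (-0.52), GSTU20 (-0.35) and UGT74C1 (-0.32) passed only when adjusted over their lists alone, and BGLU28 stood at -0.06. Leaving out replicates 1 and 2 of rpt2-3a left 308 and 158 features, and replicates 1, 2 and 3 of Col-0 left 102, 319 and 372. Of the 20 named genes 11 passed in all 6 fits without 1 array, AT3G01345, AT3G48640, AT3G22235, AT1G66810, ORA47, AT2G24040 and AT1G62310 among them.

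Under deficiency 92 features differed in rosettes, 31 higher and 61 lower in rpt2-3a, of which 46 differed at least 2-fold and 40 carried 1 gene. AT3G01345 was again lower (-5.46 ± 0.26 SE, adjusted p = 6.7e-07), with AT1G09500 (-1.68), AT2G24040 (-1.57), ORA47 (-1.49), AT5G28237 (-1.45), AT1G05340 (-1.35), AT5G03204 (-1.2), AT1G70640 (-1.14), AT1G49450 (-1.04) and AT1G62310 (-1.02). AT1G66810 (2.37), AT3G48640 (2.27), AT3G22235 (2.22), the starch-related gene QQS (1.85 ± 0.21, adjusted p = 0.0018), AT3G56210 (1.55), AT5G57760 (1.33), AT3G16670 (1.32), AT2G15830 (1.31), AT4G19830 (1.05) and AT2G21640 (0.89) were higher. The sulfur markers BGLU28 (-1.37 ± 0.28, adjusted p = 0.067) and SDI2 (-0.75 ± 0.19, adjusted p = 0.14) did not pass over all features. Both were lower when adjusted over the list alone. Among unnamed features, chosen after their values were seen, 13379325 was higher (2.96 ± 0.32, adjusted p = 0.0013). The unnamed feature 13537205 was lower (-2.51 ± 0.21, adjusted p = 0.00015). The 14 measured 26S proteasome subunits shifted up by camera, with a median of 0.25 (adjusted p = 0.007, and adjusted p = 0.59 with an estimated correlation). No subunit passed over all features, and RPN2B (0.51) alone did when adjusted over the list alone, RPT6B (0.75) and RPN11 (0.3) coming next by p. GSTU20 (0.38), ATG8F (-0.62), DFR (-0.65) and EXPA7 (0.35) passed only when adjusted over their lists alone. At both supplies 15 features were higher and 26 lower in rpt2-3a, against 0.29 and 0.66 for independent lists, and 1 changed sign. Each of the 6 arrays moved the count, to 32, 42 and 32 without replicates 1, 2 and 3 of rpt2-3a and to 56, 53 and 44 without those of Col-0. Of the 20 named genes 9 passed in all 6 fits without 1 array, AT3G01345, AT1G66810, AT3G22235, QQS and AT2G24040 among them.

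In roots at normal supply 165 features differed between genotypes, 118 higher and 47 lower in rpt2-3a, of which 61 differed at least 2-fold and 83 carried 1 gene. AT3G10040 (HRA1) was 6.47-fold higher, at 6.85 ± 0.4 in rpt2-3a and 4.16 ± 0.05 in Col-0 (n = 3; 2.69 ± 0.31 SE, adjusted p = 0.0011). AT3G27220 (1.77), AT4G10530 (1.74), AT4G25410 (1.62), AT1G59865 (1.56), AT4G10540 (1.53), AT2G05510 (1.47), AT1G15125 (1.35), AT5G10040 (1.33) and the germin-like gene AT5G38910 (1.22) were higher too. AT3G01345 (-5.24 ± 0.31, adjusted p = 5.8e-06) and AT5G15360 (-2.99 ± 0.23, adjusted p = 1e-04) were lower, as were AT1G62310 (-1.93), AT3G46800 (-1.01), XTH16 (-0.94), AT3G60090 (-0.93), AT3G03280 (-0.91), AT1G18290 (-0.88), AT4G13620 (-0.87) and AT5G52050 (-0.81). The sulfur markers SDI2 (-0.01) and BGLU28 (-0.12) did not pass, over all features or adjusted over the list alone. The 14 proteasome subunits shifted up by camera with a median of 0.168 (adjusted p = 0.0075, and adjusted p = 0.4 with an estimated correlation), while 0 subunits passed by limma over all features or adjusted over the list alone, with RPN9B (0.34), PBE2 (0.38) and RPN11 (0.21) first by p. APS3 (0.53), GSTU20 (0.41), UGT74B1 (0.3), UGT79B1 (0.36) and GH3.3 (0.35) were higher and LBD29 (-0.5) lower only when adjusted over their lists alone. Leaving out replicates 2 and 3 of rpt2-3a left 65 and 58 features, and replicates 1, 2 and 3 of Col-0 left 68, 79 and 102. Of the 20 named genes 13 passed in all 6 fits without 1 array.

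Under deficiency 220 root features differed, 141 higher and 79 lower in rpt2-3a, of which 71 differed at least 2-fold and 104 carried 1 gene. AT5G38910 was higher (2.07 ± 0.2 SE, adjusted p = 0.00037), as were the class III peroxidase AT1G49570 (1.71 ± 0.15, adjusted p = 0.00012), AT4G30380 (1.55), AT5G10040 (1.47), AT2G17850 (1.45), AT3G05770 (1.32), AT4G16260 (1.3), AT3G27220 (1.3), AT5G38540 (1.29) and AT4G19750 (1.22). AT3G01345 (-6.05 ± 0.31, adjusted p = 9.3e-07), AT5G15360 (-3.31), the cold- and abscisic acid-responsive KIN2 (-1.87), AT1G62310 (-1.77), BGLU47 (-1.17) and BGLU44 (-0.94) were lower. So were 4 genes that rose in Col-0 roots under deficiency, BGLU28 (-1.66 ± 0.28, adjusted p = 0.018), AT1G75290 (-1.53), AT4G31330 (-1.32) and AT4G37220 (-1.16), and SDI2 with them (-0.9 ± 0.17, adjusted p = 0.025). Both markers also passed when adjusted over the list alone. Among unnamed features, chosen after their values were seen, 13441502 was higher (1.83 ± 0.13, adjusted p = 1.9e-05). The unnamed feature 13537205 was lower (-1.84 ± 0.2, adjusted p = 0.00094). Of 5 auxin response genes GH3.3 was higher (0.6, adjusted p = 0.026), also when adjusted over the list alone. GSTU20 (0.57), UGT74C1 (0.42), UGT74B1 (0.26), HSP15.7 (0.47), ATG8F (-0.52), DFR (-1.21), UGT75C1 (-0.41), GI (-0.24) and ATPC1 (-0.47) passed only when adjusted over their lists alone. At both supplies 49 root features were higher and 13 lower, against 0.58 and 0.13 for independent lists. Leaving out replicates 1, 2 and 3 of rpt2-3a left 130, 43 and 145 features, and replicates 1 and 3 of Col-0 left 64 and 88. Of the 21 named genes 11 passed in all 6 fits without 1 array, AT3G01345, AT5G15360, AT4G31330 and AT4G37220 among them, while BGLU28 was lost in 4 of the 6 and SDI2 in 5.

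**Figure D3:**
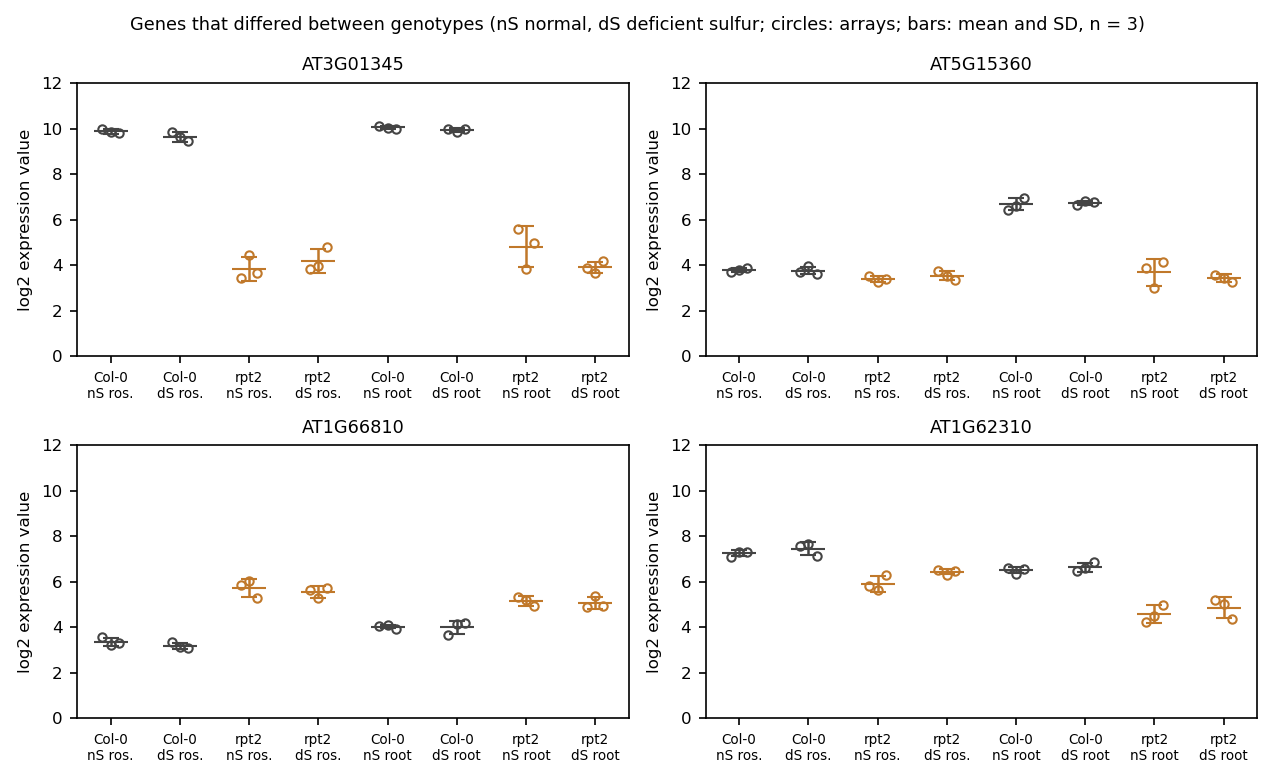
Log2 expression values of 4 genes in all 8 groups, with arrays as circles and the mean and SD of 3 arrays as bars. AT3G01345 and AT1G62310 were lower and AT1G66810 higher in rpt2-3a in both organs and at both supplies, and AT5G15360 was lower in rpt2-3a roots.

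In all 4 genotype comparisons 5 features passed with one sign, 2 higher and 3 lower in rpt2-3a. The named ones were AT3G01345, AT1G62310 and AT1G66810, the last at 2.38 and 2.37 in rosettes and 1.12 and 1.07 in roots. For AT1G62310 the call in deficient rosettes (limma adjusted p = 0.027) was lost in 5 of 6 fits without 1 array, with adjusted p up to 0.12.

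How the Col-0 response differed between organs was tested on all arrays, and 134 features passed, 94 with a higher and 40 with a lower change in roots than in rosettes. After centring each array on its median the split was 79 to 61, and after quantile normalization 80 to 59. AT1G75290 (2.86 ± 0.37 SE, adjusted p = 0.00032), AT4G37220 (2.61 ± 0.26, adjusted p = 7.3e-06) and AT3G10040 (2.56) had the largest differences toward roots among features with 1 gene, while the unnamed feature 13499857, chosen after its values were seen, stood at 3.21. Next among features with 1 gene came AT5G49750 (1.87), AT4G31330 (1.81), ORA47 (1.78), AT4G19800 (1.68), AT5G10040 (1.65) and AT4G25410 (1.6). SDI2 rose in roots and stood lower in deficient rosettes, a difference of 1.62 ± 0.27 (adjusted p = 0.0037) that also passed when adjusted over the list alone, whereas BGLU28 did not pass (0.67 ± 0.43, adjusted p = 0.69). ORA47 fell in rosettes and averaged 4.54 and 4.51 in roots at normal and deficient supply. A lower signed change in roots than in rosettes, by a rise in rosettes or a fall in roots, was measured for AT5G56880 (-1.5), AT3G50190 (-1.45), AT1G61890 (-1.26), AT5G54300 (-1.21), AT2G36690 (-1.2), AT5G52020 (-1.17), AT5G52882 (-1.04), AT4G14370 (-1.03), AT1G34050 (-1.01) and AT2G25450 (-1.01). APS3 (0.57) and UGT74B1 (0.42) were higher and BGLU23 (-0.6) lower only when adjusted over their lists alone, and none of the 8 lists fixed beforehand and tested by camera shifted. Both organs of Col-0 shared 6 features that rose, AT3G56200 among them, and 3 that fell, GSTU20 among them, against 0.12 and 0.047 for independent lists, and 1 feature that rose and 1 that fell in rosettes changed the other way in roots. Leaving out replicate 3 of deficient Col-0 rosettes left 78 features and replicate 1 of Col-0 rosettes at normal supply left 80. Of the 20 named genes 12 passed in all 12 fits without 1 array.

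Of the small lists not mentioned above, 0 of 2 detoxification genes (GSTU22, GSTU25), 0 of 3 iron genes and 0 of 1 clock gene (GI) passed by limma over all features in any of the 11 comparisons. Neither detoxification gene passed when adjusted over the list alone, the smallest unadjusted p being 0.043 for GSTU22 in the Col-0 rosette response (0.29).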

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

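The lists for hypoxia and wounding, the residual permutation and the weighing of the falling root features were chosen only after the results that prompted them were seen, and so was the criterion for selection described with the root responses. The gene results given first are differences of one response between groups of samples, each by a test of the difference itself. The hypoxia list was tested mainly between genotypes at each supply. The wound list was tested mainly for the sulfur response within each genotype.

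The root response to deficiency of AT4G31330 differed between genotypes by -1.6. The Col-0 response differed between organs, with a higher change in roots, for AT1G75290 (2.86), AT4G37220 (2.61), AT3G10040 (2.56), AT5G49750 (1.87), AT4G31330 (1.81), ORA47 (1.78), AT4G19800 (1.68), AT5G10040 (1.65), SDI2 (AT1G04770; 1.62) and AT4G25410 (1.6). The signed change was lower in roots than in rosettes for AT5G56880 (-1.5), AT3G50190 (-1.45), AT1G61890 (-1.26), AT5G54300 (-1.21), AT2G36690 (-1.2), AT5G52020 (-1.17), AT5G52882 (-1.04), AT4G14370 (-1.03), AT1G34050 (-1.01) and AT2G25450 (-1.01). The sign does not tell which organ responded. AT5G56880 rose in Col-0 rosettes from 3.25 to 4.62, whereas AT2G25450 fell in Col-0 roots from 9.06 to 8.07 and stood at 10.52 and 10.54 in rosettes. ORA47 fell in rosettes and stood at 4.54 and 4.51 in roots. Organ and medium contact differ together, and no explanation of the organ differences was tested.

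Other splits of the arrays were counted for each comparison. For the organ difference 3 of 100 splits, the real one included, gave at least as many features as the real 134, the highest other giving 171. This met the planned share under 0.05. The splits were a draw, however, and exchanging supplies within an organ breaks up any sulfur response. They therefore do not test equal responses in both organs, and chance is not excluded by them. For the root difference between genotypes 8 of 100 splits gave at least the real 3, the highest other being 8, so chance is not excluded. For the rosette difference all 100 of 100 splits gave at least the real 0, as any split must, so this comparison decides nothing. The highest other gave 692, which points to a structure of the samples: by construction, exchanging the genotypes at one supply turns a genotype effect into a difference of responses. Splits for the root difference were drawn the same way, and those for the organ difference exchange supplies within an organ. Each pairwise comparison of 3 against 3 has 10 splits, too few for a share under 0.05, and in each the real split was the 1 with the highest count. The real count and the highest other were 37 and 8 for Col-0 rosettes, 444 and 0 for rpt2-3a rosettes, 250 and 0 for Col-0 roots and 41 and 13 for rpt2-3a roots. For the genotypes they were 574 and 0 in rosettes at normal supply, 92 and 0 under deficiency, 165 and 4 in roots at normal supply and 220 and 0 under deficiency.

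AT3G10040 and AT5G10040 were higher in rpt2-3a roots at normal supply, so 40 hypoxia-responsive genes without the 3 loci seen first were tested, of which 15 were measured. Their mean was higher in rpt2-3a by 0.21 ± 0.05 SE at normal supply (camera p = 0.0096) and by 0.3 ± 0.12 under deficiency (camera p = 9.4e-05), though with an estimated correlation the p were 0.22 and 0.079. At normal supply a single array was argued against, since the smallest shift with 1 array left out was 3.61 standard errors, and under deficiency this was not tested. The list also shifted up under deficiency in roots of both genotypes, with medians of 0.217 in Col-0 (camera adjusted p = 0.0022, and adjusted p = 0.41 with an estimated correlation) and 0.377 in rpt2-3a (camera adjusted p = 1.6e-06, and adjusted p = 0.075 with an estimated correlation). A difference between the genotypes in hypoxia-responsive genes may therefore be put as a hypothesis, and oxygen in the culture vessels was not measured here.

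The root response measured smaller in rpt2-3a, so 303 rising and 197 falling features chosen on the average response of both genotypes were compared. The rising ones shifted by 0.78 ± 0.05 SE in Col-0 and 0.6 ± 0.08 in rpt2-3a. The difference was -0.18 ± 0.09, with an exact permutation p of 0.42 over 400 assignments and a residual permutation p of 0.051. A choice on the average of both responses favours neither genotype, so selection on the Col-0 response would not by itself give this difference. At these p a smaller response of the rising set was not told from no difference. How far selection made the larger gap among features called in Col-0 stays open. The planned criterion, an exact p of 0.05 or more, was met and would have left selection as an adequate explanation; it was replaced after the result because exchanging genotypes at one supply turns the genotype effect into a difference of responses, the largest other assignment giving 0.61. The rising set was higher in rpt2-3a by 0.39 ± 0.05 at normal supply and by 0.21 ± 0.08 under deficiency, and the falling set stood at -0.21 ± 0.03 and -0.07 ± 0.05, consistent with a raised or, for falling features, lowered level at normal supply, whereas SDI2 and BGLU28 were not raised there and were lower under deficiency. A single array stays open for the rising set, whose weakest difference with 1 left out was -1.49 standard errors (-0.13 ± 0.09 without replicate 1 of deficient rpt2-3a), while the falling set, of which 150 (76.1%) changed less in rpt2-3a, differed by 0.14 ± 0.05 (exact permutation p = 0.195, residual permutation p = 0.013) and by 0.13 ± 0.06 at its weakest, without replicate 1 of rpt2-3a at normal supply, which goes against a single array for these features.

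ORA47 and other rapidly induced genes fell in deficient rosettes, so 35 early wound-response genes without the 2 loci seen first were tested, of which 13 were measured. Their mean shifted by -0.33 ± 0.3 SE in Col-0 (camera p = 0.0046, adjusted p = 0.018, and adjusted p = 0.62 with an estimated correlation). In rpt2-3a it shifted by -1.04 ± 0.16 (camera p = 3.1e-12, adjusted p = 1.6e-11, and adjusted p = 0.11 with an estimated correlation), and 7 of 13 genes fell there. The list was also shifted in deficient roots, with medians of -0.213 in Col-0 (camera adjusted p = 0.0053, and adjusted p = 0.41 with an estimated correlation) and -0.327 in rpt2-3a (camera adjusted p = 8e-05, and adjusted p = 0.18 with an estimated correlation), and in deficient rosettes it was shifted in rpt2-3a against Col-0 (median -0.657, camera adjusted p = 2.7e-08, and adjusted p = 0.16 with an estimated correlation), as was the difference of rosette responses (median -0.447, camera adjusted p = 1.9e-06, and adjusted p = 0.15 with an estimated correlation). Less handling or wounding of deficient rosettes before harvest could be behind part of these changes, though handling alike in both genotypes would give no difference between them, and an effect of sulfur supply on the same genes, which the design gives, was not told from it. In Col-0 the test of a single array decided nothing, since the shift of -0.33 ± 0.3 SE lay within 2 standard errors before any array was left out. The weakest value was -0.46 standard errors (-0.13 ± 0.29 without replicate 1 of deficient Col-0). The error of 0.3 also leaves out the replicate number, which may move this list.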

How the results depend on the processing

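The settings for the counts in this part had been planned, while the wound-response and peroxidase lists were written after results had been seen. The cause was not tested for any change, also where fewer features or arrays were used. Centring arrays and quantile normalization kept every count of called features within 1.5 times.

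Testing only features with exactly 1 gene, which are fewer, gave 7 and 145 features for the sulfur response of Col-0 and rpt2-3a rosettes, 242 and 38 for the genotypes in rosettes at normal and deficient supply, 98 and 14 for the responses in roots, 65 and 96 for the genotypes in roots, 1 for the root difference and 67 for the organ difference. Fitting all 24 arrays gave 185, 778, 965 and 278 in rosettes, sharing 36, 416, 535 and 89 with the counts reported, 69 for the rosette difference, and 128 for rpt2-3a roots, 352 for the genotypes in deficient roots and 12 for the root difference, sharing 37, 182 and 3. Fitting only 2 groups, with fewer arrays, gave 5 for Col-0 rosettes, 101 for the genotypes in rosettes at normal supply, 162 and 11 for the root responses and 76 and 96 for the genotypes in roots. The replicate number as a block gave 70 for Col-0 rosettes, of which 35 were shared, and 1 for the root difference. Trend and robust gave 130, 724, 880, 241 and 19 in rosettes, the last for the difference, and 383, 154, 283, 388 and 12 in roots. Array weights gave 375 and 223 for the genotypes in rosettes and 84 for rpt2-3a roots.

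With an adjusted p and a 2-fold change, a stricter threshold, 15, 114, 129 and 46 features passed in rosettes, 88, 25, 61 and 71 in roots and 77 between organs, and the genotypes' responses shared 3 in rosettes and 15 in roots. With an unadjusted p and a 2-fold change 161 passed for rpt2-3a rosettes, 155 for the genotypes at normal supply and 208 for the rosette difference, and 95, 76, 105 and 44 for Col-0 roots, the genotypes in roots at both supplies and the root difference.

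Leaving out single arrays gave from 5 to 39 features for Col-0 rosettes, 179 to 611 for rpt2-3a rosettes, 102 to 654 and 32 to 56 for the genotypes in rosettes at normal and deficient supply, and 0 throughout for the rosette difference. In roots it gave 139 to 175 for Col-0, 10 to 31 for rpt2-3a, 58 to 159 and 43 to 155 for the genotypes, and 0 to 5 for the difference. The organ difference ranged from 78 to 174, and the shared responses from 2 to 11 in rosettes and from 8 to 28 in roots.

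Of the values of named genes with 1 array left out 977 kept direction and side of the threshold, 346 lost the call and 9 reversed, and none reversed under any other setting run. All 9 were small changes that had not passed. BGLU28 became -0.17 for the rpt2-3a rosette response without replicate 3 at normal supply, the highest being 0.3 without replicate 2. For the genotypes in rosettes at normal supply BGLU28 became 0.24 without replicate 3 of rpt2-3a, and 0.03 and 0.07 without replicates 1 and 3 of Col-0, the lowest being -0.3 without its replicate 2. In roots at normal supply BGLU28 became 0.01 without replicate 1 of rpt2-3a, and SDI2 (AT1G04770) became 0.03 and 0.12 without replicates 1 and 3 of rpt2-3a, and 0.03 and 0.1 without replicates 2 and 3 of Col-0. The lowest there were -0.24 for BGLU28 and -0.19 for AT1G04770, both without replicate 2 of rpt2-3a. Fitting only 2 groups lost 37 calls of named genes, the most of the settings other than leaving out arrays.

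Every list called by camera lost its call with an estimated correlation. By fry in limma, without adjustment over the lists, these calls were mixed, as the following examples show. The fry p was under 0.05 for autophagy and wound-response genes in the rpt2-3a rosette response and peroxidases between genotypes in deficient roots. Flavonoid genes between genotypes in rosettes at normal supply were under it too. It was over 0.05 for proteasome subunits between genotypes in deficient rosettes and wound-response genes in the Col-0 rosette response. The labels say nothing of what a replicate number shares, and over all features any pairing by number was weak. Residuals of arrays with the same number correlated across features from -0.1 to 0.24 in rosettes, over 0.1 in 3 of 18 pairs, and from -0.12 to 0.15 in roots, over 0.1 in 2 of 18. Across organs they ran from -0.17 to 0.15, over 0.1 in 5 of 48 pairs. In rosettes 7 of 12 arrays, in roots 6 of 12 and across organs 14 of 24 correlated best with their own number. More candidate partners carry another number than the own one, so these counts lean toward pairing, and no chance level was computed. Single groups of genes, such as the early wound-response list, and the block's count for Col-0 rosettes leave a shared effect of the number open. The deposited values carry no background call, so whether a dim feature was detected at all, and how far signal over background compresses its change, is open.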

Other observations

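The test on replicate numbers and the lists in this part were chosen only after results had been seen.

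The mean of the 13 early wound-response genes was lowest in replicate 1 in 7 of 8 groups. Its deviation from the group mean averaged -0.28, 0.21 and 0.07 for replicates 1, 2 and 3, and a permutation test of the replicate number over 24 arrays gave p = 0.001 (100000 resamples). Handling shared by arrays of the same number is a candidate explanation, found and tested on the same data, and neither harvest order nor batch was given. Between arrays of the same number the list in deficient rosettes differed from normal supply by -0.32, -0.23 and -0.45 in Col-0 and by -1.33, -0.96 and -0.82 in rpt2-3a.

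The 5 added lists were tested in 11 comparisons each, and of these 55 tests 27 passed by camera at the preset correlation. With an estimated correlation 5 passed before adjustment and 0 after it. The results given here are therefore examples of many calls that depend on the preset correlation. Of 62 measured class III peroxidases, AT3G03670 (0.6), AT4G08770 (0.68), AT4G08780 (0.73) and AT5G19890 (0.66) were higher in rpt2-3a than in Col-0 roots under deficiency. When adjusted over the list alone 10 were higher (camera adjusted p = 0.00058, and adjusted p = 0.11 with an estimated correlation). The 130 measured cytosolic ribosomal protein genes had a median of 0.157 in rpt2-3a against Col-0 rosettes under deficiency, with 0 passing singly by limma. The camera adjusted p was 7.5e-09, and 0.16 with an estimated correlation. Between genotypes in deficient roots the median was -0.055 (camera adjusted p = 0.0053, and adjusted p = 0.58 with an estimated correlation). For the Col-0 rosette response it was -0.075 (camera adjusted p = 0.018, and adjusted p = 0.62 with an estimated correlation). The 18 measured germin-like genes shifted in rpt2-3a roots at normal supply (camera adjusted p = 0.024, and adjusted p = 0.43 with an estimated correlation).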
